A study of Mus musculus with 72 samples.

How the data were processed

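Polyadenylated RNA was sequenced from mouse early secondary ovarian follicles, which hold an oocyte surrounded by granulosa cells, after 24 h of culture with follicle-stimulating hormone (FSH) or without it. FSH is a pituitary glycoprotein hormone that acts through the FSH receptor of granulosa cells. FSH21 was the hypoglycosylated form and FSH24 the fully glycosylated form, each given at 1 or 10 ng/ml. Per the labels' protocols, follicles were kept at 37 C and 5% CO2 in α-MEM that held GlutaMAX, fetuin at 1 mg/ml, serum albumin at 3 mg/ml and an insulin-transferrin-selenium supplement at 0.1%. RNA was extracted on RNeasy Mini columns, and 50 ng per library went into a NuGEN (Tecan) kit for messenger RNA. The 72 deposited samples were 18 libraries, each run on 4 lanes. Each of the 6 groups held 3 libraries, named by a number in the sample titles. Numbers 1, 5 and 6 were shared by the 1 ng/ml groups and by 3 untreated libraries, here the low-dose controls. Numbers 2, 3 and 4 were shared by the 10 ng/ml groups and by the other untreated libraries, here the high-dose controls. The labels call the libraries biological replicates without naming separate animals or cultures, so the p-values measure the spread between these libraries, part of which may be technical. Dose and number set could not be separated in treated libraries, and every dose was therefore compared with the controls of its own numbers.

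The deposited values were expected counts per gene as RSEM gives them, 1 column per library with the 4 lanes already merged. That they are RSEM values was taken from the column names. The submitters' processing notes name bcl2fastq, FastQC, STAR 2.7 and the mouse build mm10. The RSEM version, the gene annotation and the use of strand were not given in the sources used here. Reads of overlapping antisense genes therefore cannot be told apart, and genes with near-identical copies are uncertain, among them Gstm6, Gstm7, Ifitm1, Hspa1a, Hspa1b and the ribosomal protein genes with their pseudogenes. Of the non-zero values, 33.9% were not whole, and expected counts were rounded to whole numbers first. The file listed 56691 gene identifiers, of which 52073 were found in GENCODE M21 on GRCm38 and carried 98.7% of the counts. Positions are given from that annotation, counted from 1. The 4618 other identifiers had no position, and 2639 identifiers had no symbol. The untreated column numbered 4 matched its titles in number and index but wrote the treatment code differently.

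Counts summed to between 17.5 M and 22.5 M per library (M, mega), with a median of 21.4 M. Of the 36465 genes with a count, 18727 passed edgeR's filterByExpr by group with a minimum count of 10 and were tested. The main test was edgeR's quasi-likelihood test with robust estimation on all 18 libraries in 6 groups, TMM scaling and no block. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Adjusted p-values without another name come from this test. Chance alone gives an unadjusted p under 0.05 for a share of 0.05 of the genes tested. Levels are CPM, counts scaled to TMM-adjusted library totals, given as mean ± SD with n = 3 libraries. Fold changes are edgeR estimates on the log2 scale with their standard errors (SE). The biological coefficient of variation was 0.135. Pairs of libraries of a group varied 9.30 to 25.1 times as much as Poisson counts would. The comparisons were each treated group with its own controls, FSH21 with FSH24 at each dose and over both, the difference of each form's effect between doses, and the controls with each other.

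The 29 gene lists were FSH-induced granulosa genes, cAMP early-response genes, granulosa identity, oocyte, theca and steroidogenic, stroma and smooth muscle, endothelium, immune cells, surface epithelium, red blood cells, gap junctions, cell-cell adhesion, transzonal projections and filopodia, focal adhesion, extracellular matrix, cell cycle, apoptosis and p53, cholesterol synthesis, glycolysis, hypoxia, TGF-beta and BMP targets, YAP targets, FOXO targets, respiratory chain, heat shock, unfolded protein and amino acid response, ribosomal proteins, mitochondrial genome, and nuclear-retained RNA. Every list member was among the file's symbols, 45 fell below the count filter, and none of the red blood cell genes passed it, which left 28 lists. Lists were tested with limma's camera on log2 CPM (prior count 2) with an inter-gene correlation of 0.01, which compares a list with the other genes, and adjusted over the lists of a comparison. Camera with an estimated correlation and limma's fry were run beside it. No list called by camera stayed under 0.05 with an estimated correlation in any of the treatment and glycoform comparisons.

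The tests, the lists, the alternative settings and the rule for named genes were fixed before the data were examined. The rule named up to 8 rising and 8 falling genes with the largest fold changes among those with an adjusted p under 0.05, a mean log2 CPM of at least 2, groups that did not overlap, and a symbol other than a Gm, Rik or pseudogene model. It added up to 3 called members of each list with the smallest adjusted p, and always Fshr, Cyp19a1, Inha, Inhba, Lhcgr, Fst, Amh, Gdf9, Bmp15, Gja1, Gja4, Cdh1 and Cdh2. In the dose and control comparisons the first part alone was used, with 5 genes per direction. List members beyond these are examples chosen after their values were seen.

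Deviations of libraries from their group means were correlated between libraries of the same number. Only FSH21 at 10 ng/ml and its controls had a correlation above 0.1 for every number (0.13 to 0.21), and blocked values stand beside its results where the block changed a call. Between the other groups every same-number correlation was positive too (0.0496 to 0.235). The numbers may therefore pair those libraries as well, which counts without the block ignore. The other alternatives were DESeq2 with its size factors, limma-voom, RLE size factors, other filters on low counts, only the libraries compared, all 6 untreated libraries as 1 control group, a minimum fold change of 1.2, an adjusted p under 0.1, and leaving out each library in turn. Leaving out the libraries numbered 6 was added after seeing the data. On simulated counts with known changes, the test recovered 40.3% of genes changed 1.3-fold, 74.6% of those changed 1.5-fold and 77.3% of those changed 2-fold for FSH21 at 1 ng/ml. For FSH24 at 1 ng/ml the shares were 40.3%, 52.2% and 78.8%, for the forms compared at 10 ng/ml 40.3%, 58.2% and 81.8%, and at 1 ng/ml 49.3%, 55.2% and 78.8%, with 3.39% to 6.25% false calls. Changed genes were drawn only from those with a mean of at least 1 CPM. Each gene was drawn independently, without effects shared by a library or number. The shares therefore do not hold for genes at lower levels and can be too high for these libraries. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and Python 3.11.15 with matplotlib 3.10.9 were used.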

Results

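The transcriptomes of mouse early secondary follicles were compared after 24 h of culture. Follicles had received no FSH, hypoglycosylated FSH21 or fully glycosylated FSH24, each form at a low dose (1 ng/ml) and a high dose (10 ng/ml), to ask how the glycosylation of FSH shapes the follicle's gene expression and the contacts between its cells. There were 6 groups of 3 libraries. Mean totals were 21.4 ± 0.664 M counts in the low-dose controls and 21.7 ± 1.01 M with FSH21 and 21.2 ± 1.88 M with FSH24 at 1 ng/ml. They were 21.7 ± 0.586 M in the high-dose controls and 20.2 ± 2.37 M with FSH21 and 20.8 ± 0.502 M with FSH24 at 10 ng/ml (SD, n = 3 each). Oocyte and granulosa transcripts were abundant in untreated follicles. In the high-dose controls Gdf9, an oocyte growth factor, was at 1153 ± 60.4 CPM, Amh, the granulosa hormone of growing follicles, at 828 ± 183 CPM, and Inha, the inhibin alpha subunit, at 3194 ± 459 CPM (SD, n = 3). Gja1, the connexin of granulosa gap junctions (chromosome 10, 56377330 to 56402513), was at 2022 ± 119 CPM and Gja4, the oocyte connexin, at 166 ± 18.5 CPM. The first principal component held 16.9% of the variance, with group means of −37.0 and −28.3 for FSH21 and FSH24 at 10 ng/ml, 4.86 and 19.5 at 1 ng/ml, and 13.4 and 27.6 in the high- and low-dose controls.

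With 10 ng/ml FSH21, 1906 genes changed against the high-dose controls, 1117 higher and 789 lower, out of 18727 tested. The balance shifted without single libraries, to 737 higher and 695 lower without control number 3, 675 and 633 without treated number 4, and 669 and 593 without control number 4. Kitl, the granulosa ligand of the oocyte's KIT receptor (chromosome 10, 100015630 to 100100416, plus strand), rose from 135 ± 12.6 to 422 ± 37.5 CPM (SD, n = 3; log2 fold change 1.64, SE 0.08, adjusted p = 9.21e-10). Itga6, a laminin-binding integrin subunit (chromosome 2, 71745616 to 71858416, plus strand), rose from 692 ± 63.7 to 1774 ± 88.0 CPM (1.36, SE 0.11, adjusted p = 1.89e-07). Myo7a, an unconventional myosin of actin-based protrusions (chromosome 7, 98051060 to 98119524, minus strand), rose from 3.95 ± 0.0680 to 22.1 ± 1.23 CPM. Igfbp5, which binds insulin-like growth factors (chromosome 1, 72857932 to 72874884, minus strand), rose from 407 ± 133 to 2264 ± 317 CPM. Among the falls, Sema3g, a secreted semaphorin (chromosome 14, 31217860 to 31230352, plus strand), went from 112 ± 14.7 to 24.4 ± 0.918 CPM, and Cnnm1, a membrane protein of the cyclin M family (chromosome 19, 43440436 to 43497210, plus strand), from 27.2 ± 2.29 to 4.72 ± 0.729 CPM.

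The rule for named genes listed Ifitm1, an interferon-induced membrane protein (2.67, SE 0.22, adjusted p = 4.04e-07), Myo7a (2.48, SE 0.19), Igfbp5 (2.47, SE 0.38), and the adhesion protein Flrt1 (2.36, SE 0.34) as the largest rises on the log2 scale. After these came the cytolinker Eppk1 (2.10, SE 0.31), Clstn3 (2.09, SE 0.20), the activin beta B subunit Inhbb (1.97, SE 0.52) and the glutathione transferase Gstm6 (1.88, SE 0.20). The falls were Mug2, a protease inhibitor (−2.63, SE 0.28), Cnnm1 (−2.52, SE 0.16), the potassium channel subunit Kcnq5 (−2.30, SE 0.22), the glutamine transporter Slc38a3 (−2.23, SE 0.44) and Sema3g (−2.20, SE 0.19). Smaller falls by this rule were the tubulin Tuba8 (−2.14, SE 0.43), Sgpp2, a sphingosine phosphate phosphatase (−2.05, SE 0.16), and Mycl, a transcription factor of the Myc family (−1.88, SE 0.16). Ifitm1 and Gstm6 can share reads with near-identical copies. At least 2-fold changes were 226 rises and 108 falls. The median absolute log2 change of called genes was 0.51, and the groups did not overlap for 5189 tested genes, where chance gives 10%.

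Genes of steroid production and FSH action moved in part with FSH21 at 10 ng/ml. Of 16 FSH-induced granulosa genes, 4 rose and 1 fell, and the list did not pass the test (adjusted p = 0.0752). Star, which moves cholesterol into mitochondria, rose (1.51, SE 0.24, adjusted p = 0.000458), as did the lipoprotein receptor Scarb1 (0.73, SE 0.10), Cyp19a1, the aromatase that makes estradiol (1.40, SE 0.36, adjusted p = 0.0239), and Inhbb (adjusted p = 0.0298). Fst, the activin-binding follistatin, fell (−0.91, SE 0.22, adjusted p = 0.0185). Cyp17a1, the androgen-forming enzyme of theca cells, rose from 1.04 ± 0.0704 to 4.88 ± 1.70 CPM, and with Star it made up the 2 risen members of 13 in the theca and steroidogenic list, whose median was −0.21 while the test pointed up (adjusted p = 0.618). Fshr, the FSH receptor, did not pass at −0.58 (SE 0.26, adjusted p = 0.198), nor did Lhcgr, the luteinizing hormone receptor, at 1.44 (SE 0.75, adjusted p = 0.288), but with the replicate number as a block both were called (adjusted p = 0.000428 and 0.0268). Inha at 0.05, Inhba at 0.22 and Amh at 0.25 did not pass. Of 12 granulosa identity genes, 5 rose and 1 fell (adjusted p = 0.0145), among them Kitl, the transcription factors Gata4 (0.49, SE 0.07) and Foxl2 (0.56, SE 0.09). The list had an adjusted p = 0.597 with an estimated correlation, and 6 rose and 1 fell when adjusted over the list alone. The calls of Cyp19a1 and Fst were lost without single libraries: Cyp19a1 without treated number 3 or 4 or control number 3 (highest adjusted p = 0.0962), Fst without treated or control number 2 (0.0702). That of Inhbb was lost without treated number 3 or 4 or any 1 control (0.114).

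Oocyte, stroma, endothelial and immune lists held no called gene with FSH21 at 10 ng/ml. None of 22 oocyte genes was called, with Gdf9 at −0.11 (SE 0.08, adjusted p = 0.442) and Bmp15, its partner growth factor, at −0.13 (SE 0.11, adjusted p = 0.574). Camera placed the list down (adjusted p = 0.00508, median −0.14), and it lost that call at an adjusted p = 0.658 with an estimated correlation. No stroma and smooth muscle gene of 12 (adjusted p = 0.0919, median −0.25, and down at 0.0241 with the replicate block), endothelial gene of 9 (0.633) or immune gene of 4 (0.764, median −0.33 with the test pointing up) was called, and adjusted over the list alone 1 immune gene rose. Of 6 surface epithelium genes only Krt8, a keratin, rose (0.97, SE 0.12, adjusted p = 5.39e-05), while the list did not pass (0.0636). Of 20 cell cycle genes 7 rose and 2 fell (adjusted p = 0.0636, and up at 0.00102 with the replicate block), led by the topoisomerase Top2a (0.58, SE 0.12) and the spindle protein Tpx2 (0.49, SE 0.10), and Mki67, a marker of dividing cells, rose too (0.58, SE 0.12). Of 15 apoptosis and p53 genes 2 rose and 1 fell (0.475), including a rise of the survival gene Bcl2 (0.84, SE 0.12).

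Transcripts of junctions, adhesion and matrix changed in part at this dose of FSH21. Of 18 cell-cell adhesion genes 6 rose (adjusted p = 0.0629), among them the desmosomal cadherin Dsc2 (1.38, SE 0.14, adjusted p = 5.07e-06), Nectin2 (0.61, SE 0.09), the cadherin partner Ctnnd1 (0.43, SE 0.08) and N-cadherin, Cdh2 (0.37, SE 0.08, adjusted p = 0.00591). E-cadherin, Cdh1, did not pass (−0.26, SE 0.11, adjusted p = 0.187), but was called with the replicate block (adjusted p = 0.0410). Among 10 gap junction genes, Gja1 (−0.04, SE 0.08, adjusted p = 0.867) and Gja4 (−0.12, SE 0.11, adjusted p = 0.575) did not pass, and the junction scaffold Tjp1 rose (0.22, SE 0.06, adjusted p = 0.0292). The glial-type connexin Gjc3 fell from 39 counts over the 3 controls to 2 over the 3 treated libraries, a ratio of 0.0553 with an exact 95% counting interval of 0.00647 to 0.214 (list adjusted p = 0.618, median 0.01 with the test pointing down). This interval leaves out the spread between libraries, with controls at 0.600 ± 0.295 CPM, and is therefore too narrow. Of 12 genes of transzonal projections and filopodia, 2 rose and the actin bundler Fscn1 fell (−0.44, SE 0.10; list 0.847). Of 19 focal adhesion genes Itga6 and Zyx (0.36, SE 0.08) rose and 2 fell, including Itgav (−0.72, SE 0.12; list 0.633). Of 22 matrix genes Thbs1 (0.49, SE 0.08) and the laminin subunit Lamb2 (0.34, SE 0.07) rose (list 0.873). The call of Cdh2 was lost without control number 4 (adjusted p = 0.0635), that of Zyx without treated number 2 (0.0576), and that of Tjp1 without treated number 3 or 4 or control number 2 or 4 (up to 0.163).

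Sterol genes rose together and ribosomal protein genes fell together with 10 ng/ml FSH21. Of 20 cholesterol synthesis genes 17 rose (adjusted p = 1.36e-22, median 0.63), among them lanosterol synthase, Lss (0.86, SE 0.08). Of 87 ribosomal protein genes 69 fell and none rose (adjusted p = 1.46e-38, median −0.54), for example Rps20 (−0.66, SE 0.08) and Rplp2 (−0.64, SE 0.09), whose reads can be shared with pseudogenes. With an estimated correlation these lists had an adjusted p = 0.123 and an adjusted p = 0.27, and adjusted over the list alone 18 sterol genes rose and 73 ribosomal protein genes fell. Of 12 FOXO target genes 5 fell and 1 rose (adjusted p = 0.0313, adjusted p = 0.292 with an estimated correlation, and 0.0505 with the replicate block, which ended the call), with falls of Pik3ip1 (−0.91, SE 0.10), the insulin receptor substrate Irs2 (−0.95, SE 0.14) and Klf15 (−1.73, SE 0.27). Of 11 genes of the unfolded protein and amino acid response 3 rose (adjusted p = 8.96e-05, adjusted p = 0.292 with an estimated correlation): Ddit4 (1.07, SE 0.14), Sesn2 (0.68, SE 0.09) and Trib3 (1.19, SE 0.27), stress-induced regulators of growth signalling.

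The remaining lists at 10 ng/ml FSH21 held at most 4 called genes each. Glycolysis (17 genes, median 0.64) and hypoxia (14 genes, median 0.76) were placed up by camera (adjusted p = 0.000275 and 0.00841), each with an adjusted p = 0.658 with an estimated correlation. Only the glycolytic enzymes Hk1 (0.62, SE 0.09) and Pfkm (0.32, SE 0.08) rose and no hypoxia gene was called. The call of Pfkm was lost without treated number 3 or 4 or control number 3 (adjusted p up to 0.0871). Vegfa, a hypoxia-induced growth factor in that list, ranged from 33.4 to 585 CPM over the 18 libraries and from 88.7 to 240 CPM within the high-dose controls. Of 17 cAMP early-response genes 4 rose (adjusted p = 0.206), led by the phosphodiesterase Pde4b (1.73, SE 0.28). In the TGF-beta and BMP list 1 of 12 rose, Ltbp1 (0.78, SE 0.15; list 0.475), in the YAP list 2 of 10 rose, among them the kinase gene Nuak2 (1.37, SE 0.29), and 1 fell (0.786, median −0.02 with the test pointing up), and in heat shock 2 of 9 rose (0.786). None of 22 respiratory chain genes (0.786) or 15 mitochondrial genome genes (0.378) was called, and of 5 nuclear-retained RNAs 2 rose, among them Neat1 (0.84, SE 0.17; list 0.221). Leaving out control number 4 lowered the count of called genes from 1906 to 1262, the largest shift from 1 library.

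**Figure D1:**
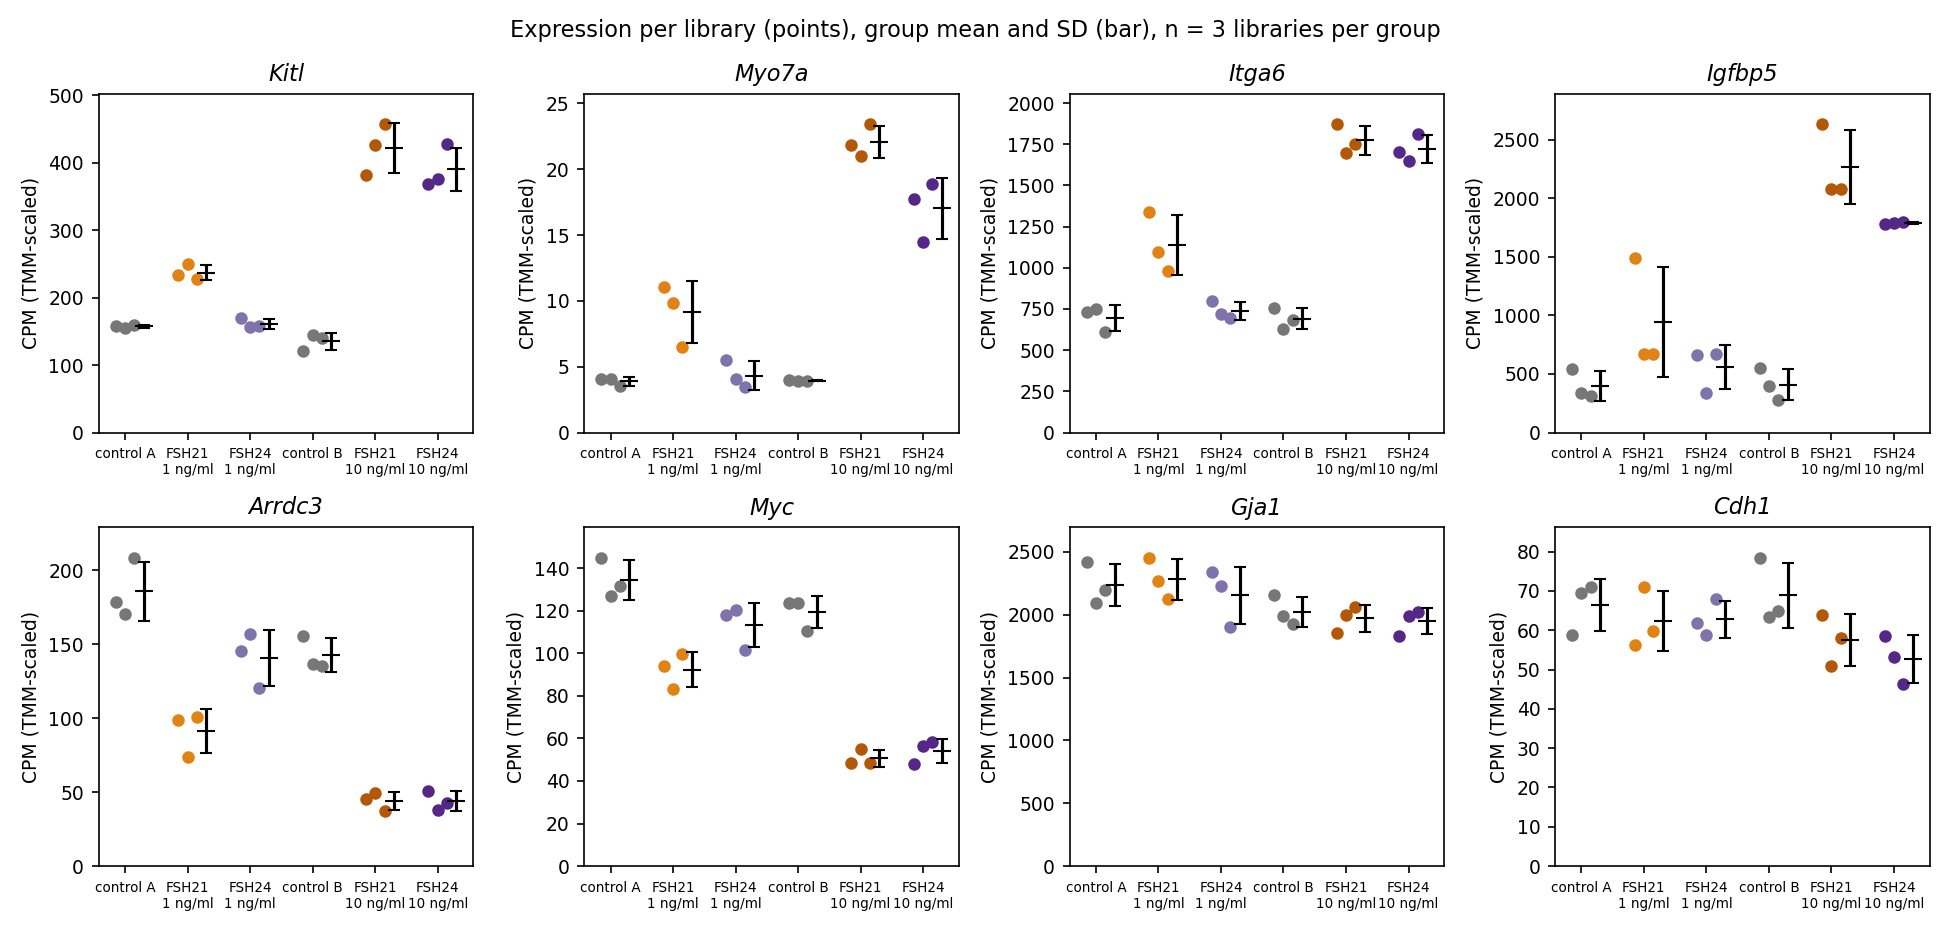
CPM of 8 genes in each of the 18 libraries by group (controls and both forms at both doses), with the mean and SD of 3 libraries per group on linear axes that start at 0. Kitl lay at 422 ± 37.5 and 391 ± 32.1 CPM with 10 ng/ml FSH21 and FSH24 against 135 ± 12.6 in their controls, and at 237 ± 11.2 and 161 ± 7.43 CPM at 1 ng/ml against 158 ± 2.67.

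With 10 ng/ml FSH24, 1577 genes changed against the same high-dose controls, 959 higher and 618 lower. Without control number 3 they were 609 higher and 602 lower, without control number 4 525 and 485, without treated number 2 606 and 436, and without treated number 4 570 and 429. Kitl rose to 391 ± 32.1 CPM (SD, n = 3; log2 fold change 1.53, SE 0.08, adjusted p = 3.01e-09) and Itga6 to 1721 ± 85.3 CPM (1.31, SE 0.11). The largest rises by the naming rule were Ifitm1 (2.28, SE 0.22), Igfbp5 (2.13, SE 0.37), Myo7a (2.11, SE 0.19), Flrt1 (2.04, SE 0.34), Eppk1 (1.98, SE 0.31), Gstm6 (1.76, SE 0.20), Gstm7 (1.61, SE 0.19) and the collagen gene Col8a1 (1.61, SE 0.17). The largest falls were Sema3g (−2.31, SE 0.19), Slc38a3 (−2.07, SE 0.44), Cnnm1 (−1.98, SE 0.16), Fgd5, an activator of Cdc42 (−1.96, SE 0.36), Sgpp2 (−1.94, SE 0.16), Kcnq5 (−1.82, SE 0.21), Mug2 (−1.74, SE 0.26) and Arrdc3, an arrestin-related adaptor (−1.70, SE 0.15). At least 2-fold changes were 160 rises and 85 falls, the median absolute log2 change of called genes was 0.48, and the groups did not overlap for 4592 genes, where chance gives 10%. Fewer genes were called without treated number 2 (1042), treated number 4 (999) or control number 4 (1010), each more than 1.5 times below 1577. The call of Slc38a3 was lost without treated number 2 (adjusted p = 0.0502).

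Granulosa and steroidogenic genes moved with FSH24 as follows. Of 12 granulosa identity genes 6 rose and 1 fell (adjusted p = 0.0181, adjusted p = 0.509 with an estimated correlation), among them Kitl, Gata4 (0.43, SE 0.07) and Foxl2 (0.43, SE 0.09, adjusted p = 0.00653). Of the FSH-induced genes 2 rose, Star (1.03, SE 0.24, adjusted p = 0.0107) and Scarb1 (0.50, SE 0.10), and Fst fell (−0.86, SE 0.22, adjusted p = 0.0288; list 0.46). Cyp17a1 rose (2.12, SE 0.46, adjusted p = 0.00702) and with Star was 1 of 2 risen theca genes (list 0.561, median −0.13 with the test pointing up). Cyp19a1 did not pass (0.89, SE 0.36, adjusted p = 0.17), nor did Fshr (−0.29, SE 0.26), Lhcgr (1.13, SE 0.75), Inha (−0.08, SE 0.15), Inhba (0.24, SE 0.14) or Amh (0.12, SE 0.18). Among 22 oocyte genes Khdc3, of the subcortical maternal complex, fell (−0.28, SE 0.08, adjusted p = 0.0372), Gdf9 (−0.15, SE 0.08) and Bmp15 (−0.15, SE 0.11) did not pass, and camera placed the list down (adjusted p = 0.000253, adjusted p = 0.509 with an estimated correlation, median −0.17). Adjusted over the list alone, 6 granulosa identity genes rose and 2 fell, 3 FSH-induced genes rose and 1 fell, and 0 oocyte genes fell. Single libraries ended the calls of Star (treated or control number 3, adjusted p up to 0.0587), Foxl2 (control number 3, 0.0550), Fst (treated or control number 2 or 4, up to 0.123) and Khdc3 (treated number 3 or 4, control number 2 or 3, up to 0.16).

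Cell-cell adhesion was placed up with FSH24, with 5 of 18 members higher and 1 lower (adjusted p = 0.0337, adjusted p = 0.461 with an estimated correlation, and 8 higher and 1 lower adjusted over the list alone). Dsc2 (1.39, SE 0.14), Ctnnd1 (0.48, SE 0.08), Nectin2 (0.53, SE 0.09) and Cdh2 (0.30, SE 0.08, adjusted p = 0.0258) rose, and Cdh1 fell from 68.9 ± 8.29 to 52.6 ± 6.11 CPM (−0.39, SE 0.12, adjusted p = 0.0446). Gja1 (−0.05, SE 0.08, adjusted p = 0.806) and Gja4 (−0.16, SE 0.11, adjusted p = 0.434) did not pass, and Tjp1 rose (0.24, SE 0.06, adjusted p = 0.0179). Gjc3 had 1 count over the 3 treated libraries against 39 in the controls, a ratio of 0.0268 with an exact 95% counting interval of 0.000661 to 0.158 (gap junction list 0.58). This interval too leaves out the spread between libraries. Of the filopodia list 1 rose and Fscn1 fell (−0.44, SE 0.10; list 0.561). Of focal adhesion genes Itga6 and Zyx (0.39, SE 0.08) rose and Itgav fell (−0.44, SE 0.12, adjusted p = 0.026; list 0.144). Of the matrix list Thbs1 (0.54, SE 0.08) and Lamb2 (0.37, SE 0.07) rose (list 0.46, median −0.06 with the test pointing up). Single libraries ended the calls of Cdh1 (treated number 3 or 4, control number 2 or 4, adjusted p up to 0.206), Cdh2 (treated number 2 or 3, control number 3 or 4, up to 0.188) and Tjp1 (treated number 3 or 4, control number 2, up to 0.0962). Those of Itgav (treated number 2 or 4, control number 3, up to 0.0946) and Fscn1 (treated number 2, 0.0502) were lost too.

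Sterol and ribosomal protein genes also moved together with FSH24. Of 20 cholesterol synthesis genes 17 rose (adjusted p = 6.25e-19, median 0.56), including Lss (0.75, SE 0.08). Of 87 ribosomal protein genes 71 fell (adjusted p = 2.43e-45, median −0.59), including Rps20 (−0.69, SE 0.08), Rps28 (−0.56, SE 0.07) and Rplp2 (−0.67, SE 0.09). Both lists had an adjusted p = 0.176 with an estimated correlation, and adjusted over the list alone 18 rose and 74 fell. The ribosomal protein share of all counts was 2.67 ± 0.164% in the high-dose controls, 1.85 ± 0.131% with FSH21 and 1.81 ± 0.172% with FSH24 (SD, n = 3). Of the unfolded protein list Sesn2 (0.55, SE 0.09) and Ddit4 (0.71, SE 0.14) rose (adjusted p = 0.0181, adjusted p = 0.509 with an estimated correlation). Of 12 FOXO targets 5 fell and 1 rose (0.0576), with Pik3ip1 (−0.70, SE 0.10) and Irs2 (−0.73, SE 0.14) lower and Sesn3 (0.66, SE 0.11) higher. Mki67 (0.65, SE 0.12), Top2a (0.61, SE 0.12) and Tpx2 (0.52, SE 0.10) were among 6 cell cycle genes that rose, and 2 fell (0.156). Krt8 (0.91, SE 0.12; surface epithelium 0.199) and Bcl2 (0.75, SE 0.12; apoptosis 0.406) rose. Hk1 rose (0.45, SE 0.09) with 1 other glycolysis gene (0.275), and Ltbp1 (0.73, SE 0.15; TGF-beta and BMP 0.561) and Nuak2 (1.28, SE 0.29; YAP 0.264) rose. Of cAMP early-response genes 1 rose (0.561), of heat shock genes 3 (0.561) and of nuclear-retained RNAs 1 (0.264). None was called among hypoxia (0.46), stroma (0.58), endothelium (0.681), immune (0.691, median −0.03 with the test pointing up), respiratory chain (0.561) or mitochondrial genome genes (0.264).

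**Figure D2:**
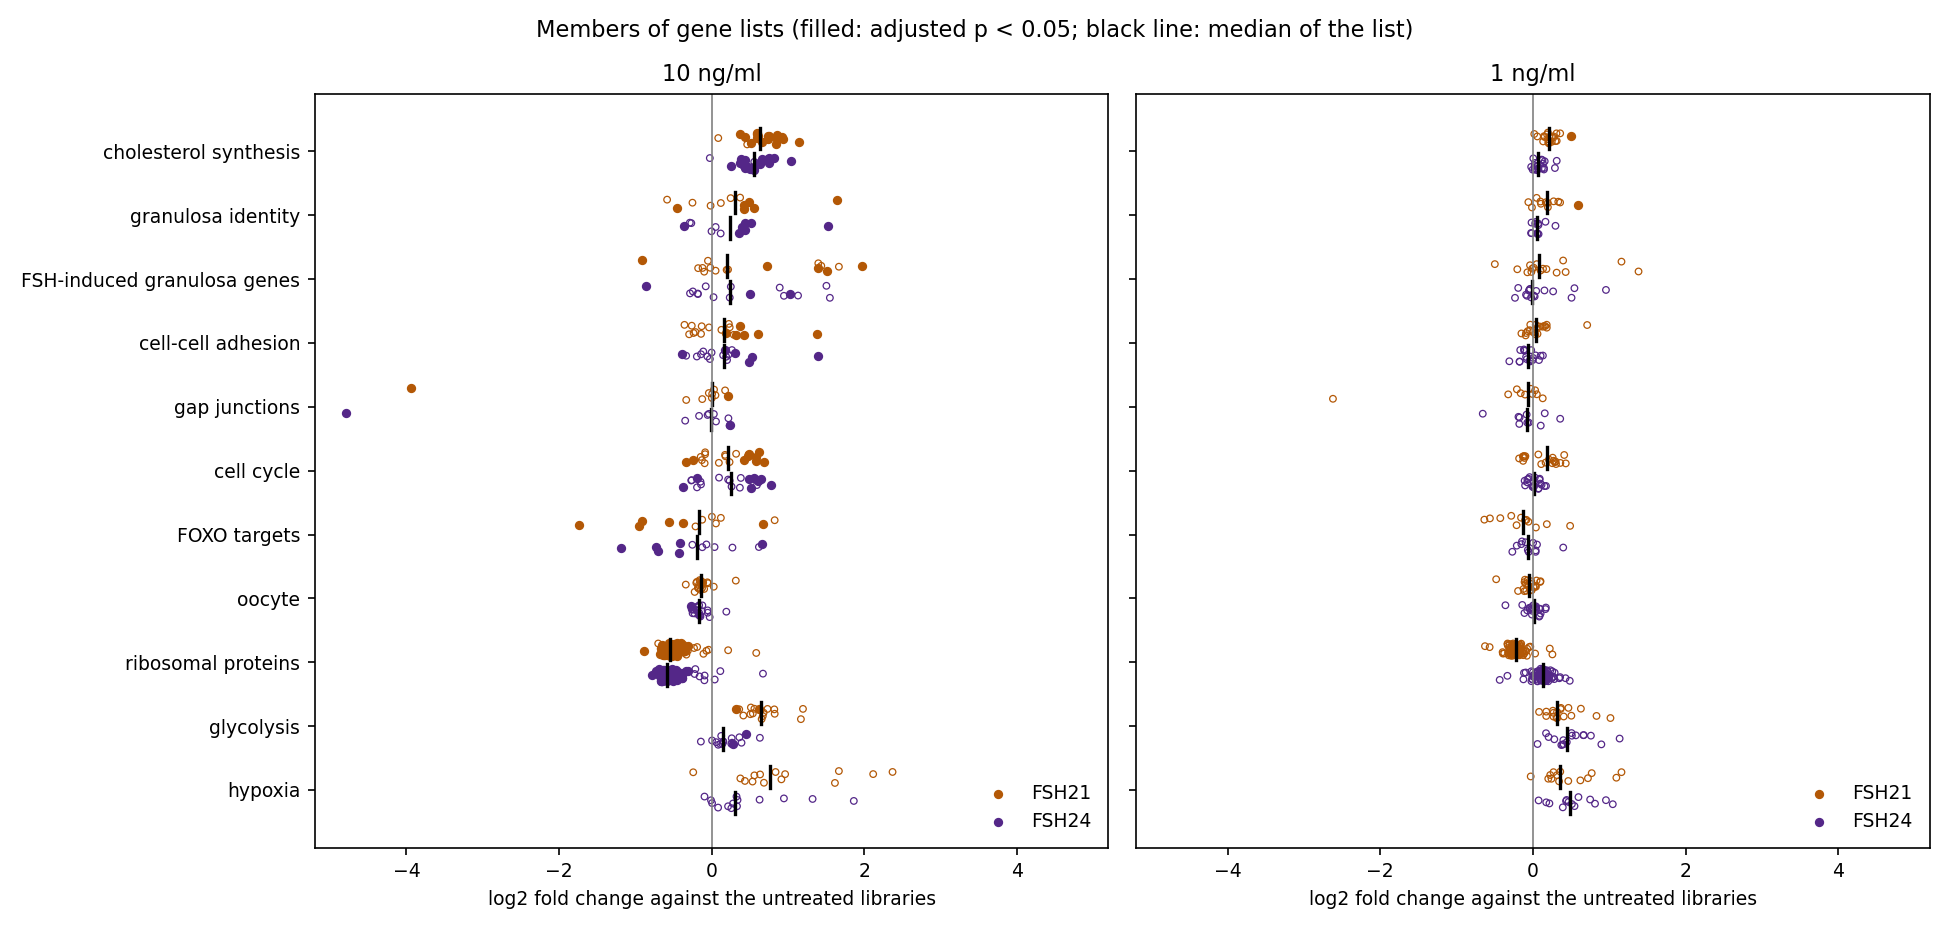
Log2 fold changes against the matching controls of the members of 11 gene lists, each point a gene, for FSH21 and FSH24 at 10 and at 1 ng/ml, with filled points for an adjusted p under 0.05 and a line at the list median. The medians of cholesterol synthesis were 0.63 and 0.56 at 10 ng/ml and 0.21 and 0.07 at 1 ng/ml, and those of ribosomal proteins −0.54, −0.59, −0.23 and 0.13.

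Both forms changed many genes in common at 10 ng/ml. Of the called genes 1324 were called with both, 798 higher and 526 lower with both and 0 in opposite directions, where independent lists of these sizes would share 57.2 and 26.0 and unchanged groups simulated against the same controls shared 0. The log2 fold changes had a correlation of 0.925 across 12571 genes, which are not independent replicates, against 0.492 on average and 0.526 at most in 20 simulations. The covariance was 0.0800 against a simulated 0.0109. The simulations drew each gene independently, so genes that move together between libraries would widen the range of values without an effect. With only 3 controls these could not be split, and part of the excess may come from the shared controls. Compared directly at 10 ng/ml, 0 genes differed between FSH21 and FSH24 by edgeR, 5 by DESeq2 and 0 by limma-voom. By edgeR 410 of 18727 genes had an unadjusted p under 0.05, less than the share of 0.05 that chance gives. The groups did not overlap for 1330 genes, where chance gives 10%. DESeq2 called Kif5b, a kinesin motor (0.25 higher with FSH21 on the log2 scale, adjusted p = 0.0150), and Usp6nl, a regulator of Rab proteins (−0.24, 0.0453). It also called Pex5l (1.91) and the gene models Gm9913 (6.33) and Gm45234 (−24.6). An estimate as large as that of Gm45234 cannot be read as a fold change. All 5 genes were named after their values were seen.

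The differences between the forms at 10 ng/ml were small for most genes called with both forms. Choosing genes called with both in these same libraries favours similar effects and narrow intervals. FSH21 minus FSH24 had the sign of the 10 ng/ml response for 835 of these 1324 genes (63.1%). Kitl differed by 0.11 and Itga6 by 0.04 on the log2 scale. The 95% interval of the difference had a median width of 0.30 to either side over all genes, and it lay within 1.5-fold for 11485 genes (61.3%) and for 1135 (85.7%) of the 1324 genes called with both. A p that misses the threshold does not show that the forms act alike. Cyp19a1 differed by 0.51 (SE 0.35), Fshr by −0.30 (SE 0.26), Lhcgr by 0.30 (SE 0.71), Inha by 0.13 (SE 0.15), Inhba by −0.02, Amh by 0.13, Fst by −0.05 and Cdh1 by 0.13 (SE 0.12), each with an adjusted p of 1. The differences of Gja1, Gja4, Gdf9, Bmp15 and Cdh2 were 0.02, 0.04, 0.04, 0.03 and 0.07, each with an adjusted p of 1. Camera placed cholesterol synthesis higher with FSH21 (adjusted p = 6.38e-07, median 0.11, 20 of 20 members positive), with glycolysis (6.38e-07, median 0.46), hypoxia (0.0002, median 0.54), the unfolded protein list (0.000449, median 0.12), FSH-induced genes (0.017) and cAMP early-response genes (0.0368). It placed stroma (0.0228), focal adhesion (0.0228) and extracellular matrix (0.0403) lower. No member of these lists was called, also when adjusted over the list alone, and with an estimated correlation each had an adjusted p = 0.611, except the matrix list with an adjusted p = 0.652 with an estimated correlation. Vegfa of the hypoxia list ranged from 120 to 505 CPM within the FSH24 libraries. The only count above 0 without 1 library was 1 gene, the model Gm9913, without FSH21 number 3.

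**Figure D3:**
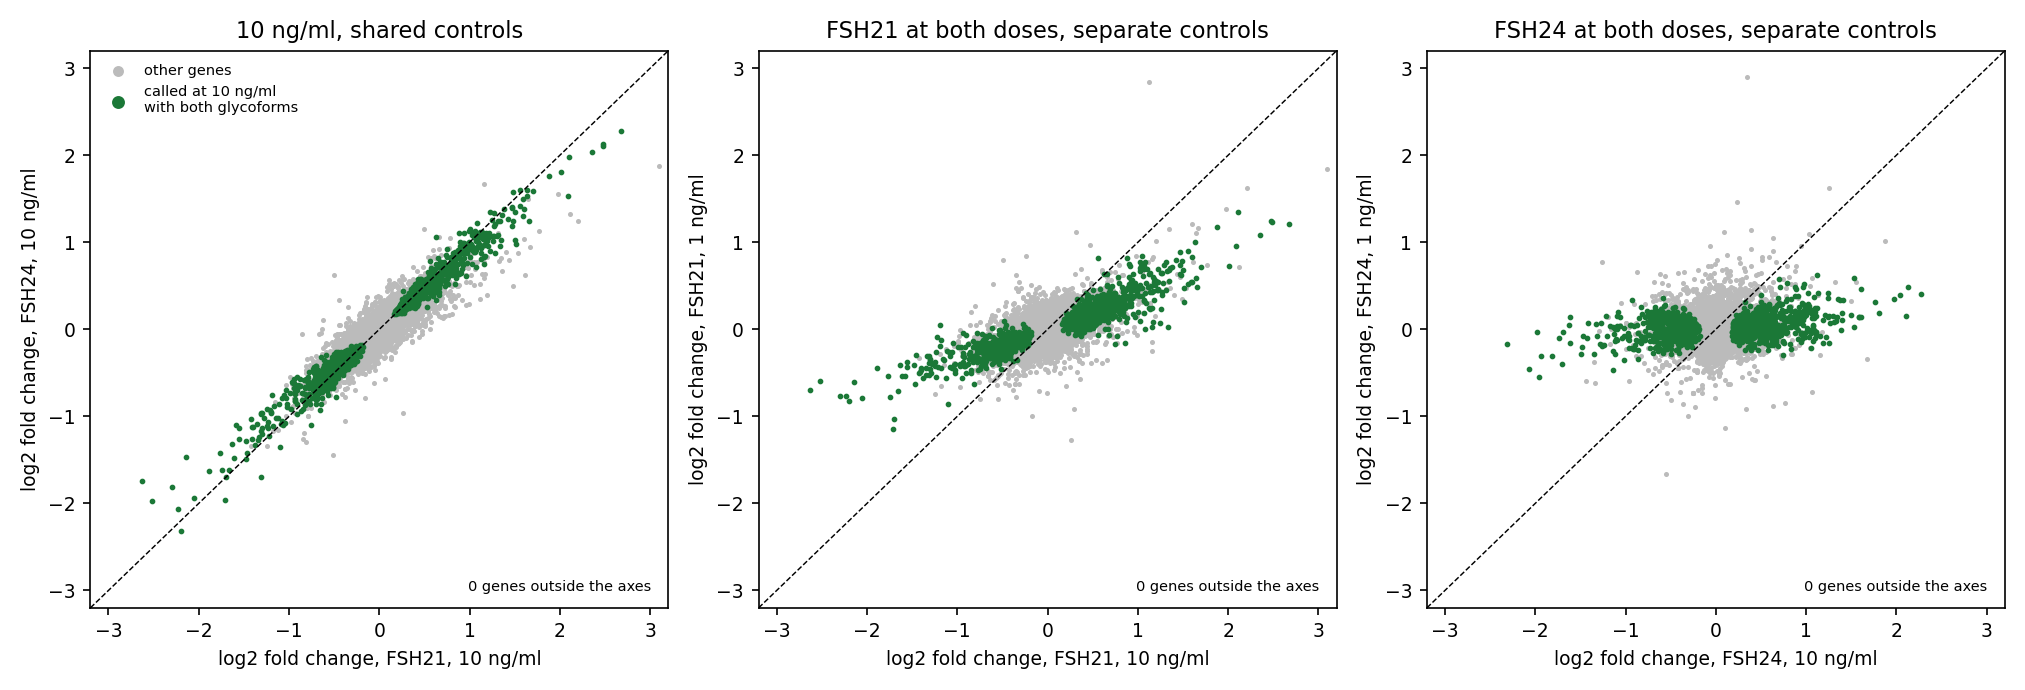
Log2 fold changes of 12571 genes against matching controls, FSH21 against FSH24 at 10 ng/ml and 10 against 1 ng/ml for each form, 1 point per gene, with the genes called at 10 ng/ml with both forms in green and a dashed line of equal change. Correlations were 0.925 for the forms at 10 ng/ml, 0.698 for FSH21 at 10 and 1 ng/ml and 0.149 for FSH24 at 10 and 1 ng/ml.

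With 1 ng/ml FSH21, 24 genes changed against the low-dose controls, 17 higher and 7 lower. Kitl rose from 158 ± 2.67 to 237 ± 11.2 CPM (SD, n = 3; 0.59, SE 0.08, adjusted p = 0.0102) and Itga6 from 697 ± 77.5 to 1139 ± 182 CPM (0.71, SE 0.10, adjusted p = 0.0163). Arrdc3 fell from 186 ± 19.9 to 91.1 ± 14.9 CPM (−1.03, SE 0.14, adjusted p = 0.0163) and the transcription factor Myc from 134 ± 9.29 to 92.3 ± 8.26 CPM (−0.54, SE 0.09, adjusted p = 0.0265). Myo7a (1.23, SE 0.19), Ifitm1 (1.21, SE 0.22), Gstm6 (1.18, SE 0.21), Gstm7 (1.00, SE 0.19), the myosin Myh14 (0.89, SE 0.17), the Ras activator Rasgrp3 (0.82, SE 0.15), Scube1 (0.80, SE 0.13) and Gask1b (0.78, SE 0.14) rose. Sgpp2 (−0.78, SE 0.14), the membrane scaffold Ank3 (−0.49, SE 0.08), the procollagen protease Adamts2 (−0.47, SE 0.09), Spsb1 (−0.45, SE 0.08) and Usp6nl (−0.27, SE 0.05) fell. Each of the 24 genes was also called, in the same direction, with both forms at 10 ng/ml. The groups did not overlap for 2430 genes, where chance gives 10%, and 1370 genes had an unadjusted p under 0.05. The count was 0 without FSH21 number 5 or control number 6, 2 (Kitl and Spsb1) without FSH21 number 1 and 5 (Kitl, Itga6, Cited2, Arrdc3 and Gm20463) without control number 1. It was 1 with only the compared libraries (Kitl) or without all libraries numbered 6 (Myo7a), these genes being named after their values were seen. DESeq2 called 111 genes, and edgeR with the replicate number as a block 226. Without control number 5, Gstm6, Gstm7, Myh14, Rasgrp3, Spsb1 and Usp6nl lost their calls, and without FSH21 number 6 Ifitm1, Myh14, Gask1b, Sgpp2, Adamts2, Spsb1 and Usp6nl did. The highest adjusted p of a named gene without 1 library was 0.289.

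Gene lists at 1 ng/ml FSH21 pointed up for sterols and down for ribosomal proteins. Camera placed cholesterol synthesis up (adjusted p = 2.82e-12, median 0.21, 20 of 20 members positive), with 1 member called over all genes and 12 adjusted over the list alone, and granulosa identity up (0.000143), with Kitl called and 3 members adjusted over the list alone. It placed ribosomal proteins (2.09e-24, median −0.23) and FOXO targets (0.012) down with no member called over all genes, and 8 and 2 members adjusted over the list alone. With an estimated correlation each of these lists had an adjusted p = 0.299. Itga6 was the 1 called focal adhesion gene (list 0.88, median −0.02 with the test pointing up). The fixed genes did not pass: Cyp19a1 was at 0.40 (SE 0.37), Fshr at 0.10 (SE 0.25), Lhcgr at −0.50 (SE 0.72), Inha at −0.02, Inhba at −0.01, Fst at −0.20, Amh at 0.20, Gdf9 and Bmp15 at 0.01, Gja1 at 0.03, Gja4 at −0.01, Cdh1 at −0.09 and Cdh2 at 0.13. In FSH21 number 6 the surface epithelium genes Krt19, Krt7 and Upk3b were at 2.06, 1.27 and 3.63 CPM, and in the control of that number at 0.547, 0.410 and 0.638 CPM.

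With 1 ng/ml FSH24, 0 genes changed against the low-dose controls by edgeR, with 1119 at an unadjusted p under 0.05, 1 by DESeq2 (the gene model Gm10240, named after its value was seen) and 0 by limma-voom. The DESeq2 estimate for Gm10240 was −24.7 on the log2 scale, too large to be read as a fold change. Kitl was at 161 ± 7.43 CPM against 158 ± 2.67 (SD, n = 3; 0.03, SE 0.08, adjusted p = 0.968), Itga6 at 739 ± 54.1 CPM (0.08) and Arrdc3 at 141 ± 18.7 CPM (−0.40). Gja1 was at −0.05 (SE 0.08), Gja4 at −0.08, Cdh1 at −0.08, Cdh2 at −0.02, Gdf9 at −0.02, Bmp15 at −0.07, Amh at −0.01, Inha at −0.05, Inhba at −0.09, Fst at −0.04, Fshr at −0.02 (SE 0.25), Cyp19a1 at −0.04 (SE 0.37) and Lhcgr at −0.19 (SE 0.71). Camera placed ribosomal proteins (adjusted p = 4.54e-08, median 0.13), respiratory chain (3.07e-05), glycolysis (5.91e-05), hypoxia (0.00738), cholesterol synthesis (0.0189) and endothelium (0.0393) up and cAMP early-response genes and extracellular matrix (0.0161 each) down. All 8 lists had an adjusted p = 0.656 with an estimated correlation, and no member was called, also when adjusted over the list alone. In FSH24 number 6 Krt19, Krt7 and Upk3b were at 11.1, 5.25 and 19.5 CPM and the endothelial and stromal gene Cd34 at 41.1 CPM, where Cd34 lay at 26.0 and 16.6 CPM in the other libraries of the group. Without FSH24 number 5, 1 gene was called, the model 2210418O10Rik.

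Compared directly at 1 ng/ml, 2 genes were higher with FSH21 than with FSH24, and 177 genes differed with the replicate number as a block. Kitl was higher by 0.56 (SE 0.08, adjusted p = 0.0211) and Cbfa2t3, a transcriptional corepressor (chromosome 8, 122625141 to 122699109, minus strand), was at 78.5 ± 11.1 against 49.3 ± 3.85 CPM (SD, n = 3; 0.67, SE 0.10, adjusted p = 0.0215). Itga6 and Myo7a, named after their values were seen, differed by 0.62 and 1.08 with an adjusted p of 0.0618 each. Over the 1324 genes called with both forms at 10 ng/ml, FSH21 at 1 ng/ml had the sign of the 10 ng/ml response for 1293 (97.7%) and FSH24 for 795 (60.0%), and the high- against the low-dose controls for 577 (43.6%). A response score, chosen after seeing the data, was 0 for a dose's own controls and 1 for log2 CPM changes equal to both forms' mean edgeR log2 fold changes at 10 ng/ml. At 1 ng/ml it was 0.387 ± 0.0669 with FSH21 and 0.0859 ± 0.0397 with FSH24 (SD, n = 3). At 10 ng/ml, where it is near 1 by construction, it was 0.955 ± 0.0390 and 0.876 ± 0.0571. The difference of 0.301 at 1 ng/ml had an exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow, and FSH24 at 1 ng/ml against its controls had p = 0.2. Of the other fixed genes, Cyp19a1 differed by 0.43 (SE 0.37), Lhcgr by −0.31 (SE 0.72), Fshr by 0.12, Inha by 0.03, Inhba by 0.08, Amh by 0.21 and Fst by −0.16. Gdf9 differed by 0.03, Bmp15 by 0.09, Gja1 and Gja4 by 0.08, Cdh1 by −0.01 and Cdh2 by 0.15, none past the threshold. Intervals of the difference lay within 1.5-fold for 11025 genes (58.9%), and the groups did not overlap for 2784 genes, where chance gives 10%.

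Ribosomal protein genes were lower with FSH21 than with FSH24 at 1 ng/ml by camera (adjusted p = 1.09e-43, median −0.36), with none called over all genes and 70 of 87 adjusted over the list alone. Cell-cell adhesion was placed higher (0.0025) with 3 members adjusted over the list alone, and these lists each had an adjusted p = 0.195 with an estimated correlation. Cholesterol synthesis (4.31e-05), granulosa identity (0.0385) and nuclear-retained RNA (0.0351) were placed higher and respiratory chain (1.82e-05) lower, each with an adjusted p = 0.582 with an estimated correlation. Among their members only Kitl was called over all genes. The surface epithelium list did not pass (0.388, median −0.87 with the test pointing up), and the libraries with the highest Krt19 were FSH24 number 6 at 11.1 CPM and FSH21 number 6 at 2.06 CPM. The count of 2 genes became 0 without FSH21 number 1, FSH21 number 5, FSH24 number 5, FSH24 number 6 or all libraries numbered 6, 4 without FSH24 number 1 (Myh14 and Myo7a joining) and 7 without FSH21 number 6. DESeq2 called 204 genes and limma-voom only Kitl.

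Over both doses, 0 genes differed between FSH21 and FSH24 by edgeR, with 967 at an unadjusted p under 0.05, 26 by DESeq2 and 0 by limma-voom. With the replicate number as a block edgeR called 36 genes. Same-number correlations between the forms were all positive (0.0719 to 0.235), though not every one passed 0.1, so the numbers may pair these libraries. The smallest adjusted p was 0.0948, for Kitl (0.34 higher with FSH21) and Usp6nl (−0.21), named after their values were seen. Cyp19a1 differed by 0.47 (SE 0.25), Cdh2 by 0.11, Amh by 0.17, Fst by −0.11, Fshr by −0.09, Inha by 0.08, Inhba by 0.03, Cdh1, Bmp15 and Gja4 by 0.06, Gja1 by 0.05, Gdf9 by 0.04 and Lhcgr by 0.00, none past the threshold. Intervals of the difference had a median width of 0.21 to either side and lay within 1.5-fold for 12904 genes (68.9%). Camera placed ribosomal proteins lower with FSH21 (adjusted p = 7.97e-28, median −0.16), and cholesterol synthesis (7.37e-11, median 0.13) and cell-cell adhesion (0.0241) higher, each with an adjusted p = 0.383 with an estimated correlation. Stroma (0.01) and respiratory chain (0.00279) were placed lower and granulosa identity (0.0476) and nuclear-retained RNA (0.0491) higher with an adjusted p = 0.647 with an estimated correlation, and FOXO targets (0.0491) lower with an adjusted p = 0.46 with an estimated correlation. Adjusted over the list alone, 3 granulosa identity, 1 cell-cell adhesion and 1 cholesterol gene were higher and 1 FOXO target lower. Without 1 library up to 3 genes were called: Kitl, P3h2 and Gm4540 without FSH21 at 10 ng/ml number 2, Gm9913 without its number 3, and Grb14 and Myo7a without FSH21 at 1 ng/ml number 6.

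The effect of each form differed between the dose groups for some genes. Each dose had its own set of numbers, so a different response of the sets to FSH cannot be told apart from an effect of dose. For FSH21, 51 genes had a different effect at 10 than at 1 ng/ml (19 with a higher and 32 with a lower log2 change at 10 ng/ml), and for FSH24 458 (226 and 232). For FSH21 this balance was 3 to 19 without number 3 at 10 ng/ml and 35 to 33 without number 1 at 1 ng/ml. With the replicate number as a block the counts were 229 for FSH21 (116 higher and 113 lower) and 1180 for FSH24. The FSH24 effect on Kitl was 1.50 higher at 10 ng/ml (SE 0.11, adjusted p = 1.23e-06) and the FSH21 effect 1.05 higher (SE 0.11, adjusted p = 0.000165). The naming rule listed for FSH24 Snrnp35 (0.76, SE 0.18), Enc1 (0.70, SE 0.10), Nbeal2 (0.64, SE 0.15), Zhx2 (0.60, SE 0.13) and Zswim8 (0.52, SE 0.10) with higher effects at 10 ng/ml, and no gene for FSH21. The rule asked that treated libraries at 10 ng/ml plus low-dose controls not overlap high-dose controls plus treated libraries at 1 ng/ml. Listed genes therefore also had controls that did not overlap, as Snrnp35 at 6.02 ± 0.138 CPM in high-dose and 8.44 ± 0.448 CPM in low-dose controls. Larger dose differences such as that of Kitl did not meet this rule. Lower effects at 10 ng/ml were listed for Sco2, a copper chaperone of cytochrome oxidase (−1.09, SE 0.27), the copper chaperone Atox1 (−0.57, SE 0.14), Trmt112 (−0.54, SE 0.13), Selenow (−0.48, SE 0.11) and Taf10 (−0.48, SE 0.11). Enc1 and Zswim8 kept their calls without each library in turn, and the other 8 genes lost theirs without FSH24 number 4 at 10 ng/ml. At that dose calls were also lost without FSH24 number 2 (Snrnp35, Sco2, Atox1, Trmt112, Taf10) and control number 2 (Snrnp35, Nbeal2, Zhx2, Sco2, Atox1, Trmt112), 3 (Snrnp35, Sco2, Atox1) or 4 (Snrnp35, Sco2, Atox1, Selenow, Taf10). At 1 ng/ml they were lost without FSH24 number 1 (Snrnp35, Nbeal2, Sco2, Trmt112, Taf10), 5 (Snrnp35, Sco2, Atox1) or 6 (Snrnp35, Nbeal2, Sco2, Atox1, Trmt112, Selenow). The same held without control number 1 (Sco2), 5 (Snrnp35, Nbeal2, Sco2, Atox1, Trmt112, Selenow, Taf10) or 6 (Snrnp35, Zhx2, Atox1), with an adjusted p up to 0.104. The FSH21 count of 51 was at most 32 without FSH21 number 3 (22) or 4 (25) or control number 3 (27) or 4 (22) at 10 ng/ml, or FSH21 number 5 (32) or 6 (20) or control number 1 (30) or 5 (24) at 1 ng/ml. The FSH24 count of 458 was at most 302 without FSH24 number 2 (299) or 4 (212) or control number 2 (302) or 4 (253) at 10 ng/ml, or FSH24 number 5 (293) or control number 5 (221) at 1 ng/ml.

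The untreated libraries of the number sets were compared to measure how far the sets differed without FSH. By edgeR 0 genes differed between high-dose and low-dose controls, with 1020 at an unadjusted p under 0.05, 1 by DESeq2 (Sfpq, a nuclear RNA-binding protein, −0.19, adjusted p = 0.0168, named after its value was seen) and 0 by limma-voom. Kitl was at 135 ± 12.6 and 158 ± 2.67 CPM and Itga6 at 692 ± 63.7 and 697 ± 77.5 CPM in the high- and low-dose controls (SD, n = 3). The groups did not overlap for 2053 genes, where chance gives 10%. Without control number 1, 1 gene was called, the model Gm20463. Lhcgr was at 7.15 CPM in control number 1. Across doses, whose controls are separate, log2 fold changes at 10 and 1 ng/ml had a correlation of 0.698 across genes for FSH21, where 20 simulations of unchanged groups reached 0.0750, and of 0.149 for FSH24, where they reached 0.0820. Each gene was drawn independently in these simulations, so their ranges can be too narrow.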

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

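Of the tests below, those of scaling, pseudogene copies, translation factors, RNA of other cells, delivered dose, both tests of the hypoxia spread and the reassigned doses were chosen after the results were seen. No group of 3 libraries was tested for single deviating values.

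The results listed here were picked out because the effect of a hormone form differed between doses in a test of that difference. Dose and number set coincide in the treated libraries, so this test cannot tell them apart. For FSH21 this held for 51 genes, with the smallest adjusted p for Kif5b, a kinesin motor (0.75), Kitl (1.05), the malic enzyme Me3 (−1.18), Cnnm1 (−1.93) and Cables1 (−1.22), as log2 effect at 10 minus that at 1 ng/ml. For FSH24 it held for 458 genes, with the smallest adjusted p for Kitl (1.50), Cnnm1 (−1.95), Cables1 (−1.25), the membrane scaffold Ank3 (−1.08) and Spsb1 (−0.98). The naming rule added Snrnp35 (0.76), Enc1 (0.70), Nbeal2 (0.64), Zhx2 (0.60), Zswim8 (0.52), Sco2 (−1.09), Atox1 (−0.57), Trmt112 (−0.54), Selenow (−0.48) and Taf10 (−0.48) for FSH24.

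Among 40 drawn splits of the libraries between treated and untreated, 8 gave as many genes as the FSH21 dose difference, the highest other 1950 against the real 51, and 3 as many as that of FSH24, the highest other 701 against 458. All 7 and all 2 of these other splits kept the real grouping of the 10 ng/ml libraries, and no split without it passed 1 gene. With libraries reassigned between doses, 3 of 40 splits gave as many genes for FSH21 (highest other 87) and 4 for FSH24 (highest other 1070), each of the other ones with the real doses of the treated libraries kept. These counts cannot decide whether chance gave either dose difference. A split that keeps the 10 ng/ml grouping keeps the response at that dose by construction, a structure of the samples, so these splits do not test the dose difference well.

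Ribosomal protein transcripts were lower at 10 ng/ml with both forms. The gap of the list's median to that of all genes was −0.54 with FSH21 and −0.59 with FSH24, but scaling sets the median of all genes to 0, so a fall of these transcripts and a rise of most others cannot be told apart. A bias against short transcripts is argued against by genes matched in length and level, whose median moved by 0.0194 and 0.0294. Assignment of reads to pseudogene copies is argued against by the pseudogene sum, which moved by −0.58 and −0.61 (SE 0.11), down like the genes themselves. The medians of 20 translation factors, proteins that work with the ribosome, were −0.33 and −0.37, lower than in 100% of matched random lists. Each random list drew its genes independently, so a list whose genes move together can lie outside them, and this share cannot decide. A lower level of translation transcripts relative to others in FSH-treated follicles stays open as a hypothesis.

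The response at 1 ng/ml was larger with FSH21 than with FSH24. RNA of other cells in FSH24 number 6, where Krt19 was at 11.1 CPM, is argued against as the whole cause by the response scores of the other FSH24 libraries, at most 0.0969 against at least 0.312 with FSH21. Sequencing depth is argued against by FSH24 numbers 5 and 6, which had higher totals (22.1 M and 22.5 M) than FSH21 number 6 (20.5 M) and lower scores (0.0419 and 0.119 against 0.312), while thinning to equal totals moved the scores little and left a difference of 0.298. A difference in delivered dose and a difference in potency of the forms cannot be told apart, because the labels give nominal doses only. The FSH24 effects at 1 and 10 ng/ml had a correlation of 0.149 across genes, above the highest simulated value of 0.0820. Those of FSH24 at 1 and FSH21 at 10 ng/ml had 0.232, with at most 0.0477 simulated. These simulations drew each gene independently, so their ranges can be too narrow. Both forms at 1 ng/ml had 0.426, below the mean of 0.496 simulated for shared controls without an effect. That simulation left FSH21 unchanged too, so this value cannot decide. A weak FSH24 response at 1 ng/ml stays open.

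Hypoxia transcripts differed between libraries of 1 group by up to 3.65-fold in the list's mean. Libraries of 1 number deviated together with a mean product of 0.117 (one-sided permutation p = 0.101, 18 libraries), so shared conditions cannot be told apart from chance with 3 libraries per number. Ribosomal RNA shares went with the deviations at r = −0.367 (permutation p = 0.167) and at −0.186 without the 2 libraries farthest from the median rRNA deviation, with −0.837 within the 1 ng/ml set and 0.498 within the 10 ng/ml set, which leaves carry-over open. No biological explanation was tested, since no label describes oxygen or follicle size per library.

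With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. As many genes as in the real grouping came in 1 of 10 splits with FSH21 at 10 ng/ml (real 1906, highest other 0), 1 with FSH24 at 10 ng/ml (1577, 0), 1 with FSH21 at 1 ng/ml (24, 1) and 10 with FSH24 at 1 ng/ml (0, 1). The count was 10 for the forms at 10 ng/ml (0, 0), 1 for the forms at 1 ng/ml (2, 0) and 10 for the controls (0, 1). Where the real count is 0, every split gives as many by construction, so these splits test nothing. As many lists came in 4 of 10 splits with FSH21 at 10 ng/ml (real 8, highest other 10), 7 with FSH24 at 10 ng/ml (6, 10), 6 with FSH21 at 1 ng/ml (4, 10) and 3 with FSH24 at 1 ng/ml (8, 9). For the forms they came in 4 splits at 10 ng/ml (9, 10) and 3 at 1 ng/ml (6, 11). Over both doses 40 of 40 drawn splits gave as many genes as the real 0, again by construction. As many lists as the real 8 came in 13 of these 40 splits (highest other 10). The highest other gene count, 146, came from a split that kept the forms at 1 ng/ml and mixed them at 10 ng/ml, which points to structure.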

How the results depend on the processing

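Leaving out all libraries numbered 6 was chosen after the results were seen, and the other alternatives were fixed before. Of 2367 refitted values of named genes, 2105 kept their side of the threshold, 259 lost a call (258 of 1626 with 1 library left out, 1 of 248 with RLE size factors), 3 gained one and 0 reversed, and all 245 values with a DESeq2 adjusted p kept theirs. Many named genes were chosen for large changes or small p-values in these data, and fixed genes that stayed uncalled count as kept. These shares therefore do not describe calls in general. Of 171 gene counts 104 stayed within 1.5 times and 67 moved. The cause was not tested unless given here. Lanes were merged in the file, so the planned comparison of lanes was not run.

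In the order FSH21 at 1 ng/ml, forms at 1 ng/ml, forms over both doses, FSH21 dose difference and FSH24 dose difference, counts of 24, 2, 0, 51 and 458 became 46, 10, 2, 99 and 751 at an adjusted p under 0.1, as a looser threshold must give. DESeq2 gave 111, 204, 26, 167 and 816, with 1 for FSH24 at 1 ng/ml, 5 for the forms at 10 ng/ml and 1 for the controls. Without a filter beyond 1 count they were 59, 65, 9 and 102 (FSH24 dose difference 455). Limma-voom gave 1 and a minimum fold change of 1.2 gave 0 for the forms at 1 ng/ml. With only the libraries compared, which are fewer, FSH21 at 1 ng/ml had 1 gene and the forms at 1 ng/ml 0, and without libraries numbered 6 also 1 and 0, with dose differences of 14 and 225. All 6 untreated libraries as 1 control group gave 2898 genes with FSH21 at 10 and 57 at 1 ng/ml. The share of higher genes moved from 37.3% to 26.2% with limma-voom for the FSH21 dose difference, from 49.3% to 34.7% with only the libraries compared and 38.2% without number 6 for FSH24, and from 70.8% to 82.5% with pooled controls for FSH21 at 1 ng/ml. For the forms at 1 ng/ml, 84 of 204 genes were higher with DESeq2 and 21 of 65 without the filter, against 2 of 2.

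By the rule of a correlation above 0.1 for every number, only FSH21 at 10 ng/ml and its controls counted as paired. There the replicate block gave 2819 genes, 1893 of them among the 1906 without it. Among named genes and camera lists it changed no call beyond those given in the report. Elsewhere correlations of same-number deviations reached 0.0496 at the lowest and 0.235 at the highest. By deviations from group means, all 18 libraries were closest to one of their own number. Candidates were the libraries of the other groups at their dose and its controls. Numbers may therefore pair libraries in the other groups too, though the labels do not say what a number stands for. With the replicate block there were 2547 genes with FSH24 at 10 ng/ml, 226 with FSH21 at 1 ng/ml, 177 and 36 for the forms at 1 ng/ml and over both doses, 229 (116 higher and 113 lower) and 1180 for the dose differences of FSH21 and FSH24, and 8 lists in place of 4 with FSH21 at 1 ng/ml.

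With an estimated correlation 0 lists were called in each of the 7 comparisons with lists, in place of 8, 6, 4, 8, 9, 6 and 8. Fry called 7 with FSH21 and 5 with FSH24 at 10 ng/ml (5 and 4 of them also by camera), 0 with FSH21 at 1 ng/ml, 0 with FSH24 at 1 ng/ml, 0 for the forms at 10 ng/ml, 2 at 1 ng/ml and 0 over both doses. In place of 0.925 for the forms at 10 ng/ml, correlations without shared controls were 0.698 for FSH21 at both doses, 0.149 for FSH24 at both doses, 0.232 for FSH21 at 10 and FSH24 at 1 ng/ml, and 0.679 for FSH24 at 10 and FSH21 at 1 ng/ml. With 1 library left out, counts ranged from 1262 to 1646 and 999 to 1427 with FSH21 and FSH24 at 10 ng/ml, 0 to 21 and 0 to 1 at 1 ng/ml, 0 to 1 and 0 to 7 for the forms at 10 and 1 ng/ml, and 0 to 3 over both doses. They ranged from 20 to 68 and 212 to 527 for the dose differences of FSH21 and FSH24, and 0 to 1 for the controls, with fewer libraries in each fit. At 17.5 M to 22.5 M counts per library, 18727 of 36465 genes with a count could be tested.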

Other observations

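The gene families in this part were chosen after the results were seen, and their members were tested with all other genes.

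Fatty acid synthesis and desaturation genes rose with both forms at 10 ng/ml, 11 of 18 with each and none lower (medians 0.43 and 0.40). Among them was the elongase Elovl6 (log2 fold change 1.31, SE 0.13, adjusted p = 5.74e-06 with FSH21 and 1.07, SE 0.13, adjusted p = 6.61e-05 with FSH24). The others included the desaturase Fads2 (0.92 and 0.81), fatty acid synthase, Fasn (0.63 and 0.63), and Srebf1, a transcription factor of lipid synthesis (0.58 and 0.45). Mu-class glutathione transferases, which conjugate electrophiles, rose in 5 of 6 genes with FSH21 and 4 of 6 with FSH24, for example Gstm1 (0.83 and 0.87) and Gstm2 (1.13 and 1.09), and 2 of 6 rose with FSH21 at 1 ng/ml. Their copies are alike in sequence and share reads.

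Of 24 ADAMTS and ADAMTS-like genes, secreted proteases and relatives of the matrix, 6 fell and none rose with each form at 10 ng/ml, among them Adamts2 (−1.02, SE 0.09 and −0.89, SE 0.09), Adamts5 (−1.23 and −1.06) and Adamtsl2 (−1.66 and −1.62). Insulin and IGF signalling genes moved both ways, 4 of 22 higher and 5 lower with FSH21 and 3 higher and 5 lower with FSH24. Igf1, the growth factor (−0.88, SE 0.09 and −0.66, SE 0.09), the receptor adaptor Grb14 (−1.35 and −1.09) and the kinase subunit Pik3r1 (−1.30 and −0.96) fell with both, while Igfbp5 and Pik3r3 (0.63 and 0.75) rose. Wnt4, a granulosa signal, rose (1.51, SE 0.17 and 0.98, SE 0.17). Esr2, the estrogen receptor of granulosa cells (−0.69, SE 0.07 and −0.53, SE 0.07), and the nitric oxide synthase Nos2 (−1.16 and −0.88) fell. Of 20 semaphorins 6 rose and 3 fell with FSH21 and 4 rose and 3 fell with FSH24, Sema5b (1.22 and 1.35) higher and Sema6b (−1.30 and −1.20) lower.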
